A study of Mus musculus with 36 samples.

How the data were processed

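The deposited scanner files of all 36 arrays were read. Per the file headers they hold mean spot and median local background intensity for Cy3 and Cy5, extracted with Agilent Feature Extraction 9.1.3.1 (the submitters' notes name 8.1 and 9.1). Per the file headers the scanner software also gives background-subtracted and dye-normalized intensity and a log10 ratio of Cy5 over Cy3. The series tables deposited by the authors give treated over vehicle RNA as log2 for the E2 set and as log10 for the BPA and HPTE set, which the slopes against the scanner log10 ratio (3.32 and 1) show. Other columns of the deposited files are spot marks of 0 or 1, per the file headers, for outliers, saturation and signal well above background. Between 65.55% and 96.62% of gene spots per array and channel were well above background. The top shares, 93.33% and 96.62%, were the 2 channels of 1 array (aERKO with HPTE at 24 h, treated RNA in Cy5). The next highest was 80.05%.

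Each array holds 43379 gene spots of 41174 probes. Probe names were brought to current symbols with a mouse gene table: 22951 by accession, 6659 by symbol and 3109 by synonym, while 8455 kept the name in the file, giving 27670 genes. A gene is its probe with the highest mean intensity. Background was corrected by normexp (offset 50), ratios were normalized by loess within each array, and the sign was turned so that every ratio is treated over vehicle. The 2 dye-swapped arrays of a condition were averaged, since both carry the same RNA. A probe was kept where the treated or vehicle RNA was well above background on both arrays of at least 3 of the 18 conditions. That left 20814 genes, of which 20764 had a value in every condition and were tested, and 50 were left out.

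Responses and their differences between genotypes were tested in limma (lmFit and eBayes) with 1 mean per genotype and time. The 3 compounds are the 3 values of a mean, and the spread between compounds is pooled over all genotypes and times. The vehicle label (9 labels, 3 per genotype) was a random block with a fitted correlation of 0.59. Differences between compounds over the genotypes used a second limma model with the compound as a factor and a block correlation of 0.582. Vehicle uteri were compared in limma on the vehicle channel after quantile normalization of mean intensities (Aquantile), with 1 value per vehicle label, averaged from 8 arrays for oil and 2 for each saline label. Adjusted p values are Benjamini-Hochberg values over all genes tested, and a gene passed at an adjusted p under 0.05. The test of a response therefore asks what the compounds share.

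The block weights the 3 values unequally, and the oil label of a genotype covers both times. A fitted response and its p at 1 time therefore also draw on the oil pools of the other time. The fitted response can thus lie outside the range of the 3 compounds. That held for 1432 of 8409 genes in WT uteri at 2 h (17%), 136 of 4200 at 24 h (3.24%), 446 of 4945 in KIKO uteri at 2 h (9.02%) and 8 of 121 in aERKO uteri at 2 h (6.61%), with 0 opposite in sign to the plain mean. The report therefore prints the plain mean ± SD of the compounds beside the adjusted p of the model. Medians of gene lists are medians of fitted values. A 2-fold change in 1 condition means a mean log2 ratio of at least 1 in size, with both arrays at 0.5 or more in the same direction, and carries no test.

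The choice of tests, the 28 gene lists (17 of pathways, 11 of cell types, 333 genes of which 322 were measured), the alternatives and the rule for naming genes were fixed before the data were examined. By that rule a response names up to 8 largest rises and 4 largest falls among genes past the test with the same sign on all 6 arrays. A difference names up to 6 highest and 4 lowest genes. Each list names up to 4 members with the largest change past the test, or where none passed up to 2 with the smallest p as values, and Esr1 and Pgr are always eligible. The text prints a choice of these. Lists were tested with camera in limma at a preset correlation of 0.01 and again with an estimated correlation, and adjusted over the 28 lists.

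Chosen after the data were seen were 10 further contrasts (compounds within WT uteri, and 2 h against 24 h within and between genotypes), the blocks of distinct vehicle RNAs and of scan day, the fit without 1 doubted array, and the cilia gene list. The doubted array is aERKO with HPTE at 24 h with treated RNA in Cy5, whose ratios correlated at -0.035 with its dye swap. The contrasts of compounds within WT uteri set 1 pool pair against 1, with the spread of the KIKO and aERKO pools and the distinct vehicle RNAs as a random block (correlation 0.536), and no gene is called from them. Median 95% half-widths were 0.551 for E2 contrasts and 0.375 for BPA against HPTE.

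Vehicle labels were compared by the correlation, between the 2 dye orientations, of the vehicle-channel difference of 2 conditions. The median between saline and oil was 0.593 in WT, 0.589 in KIKO and 0.0485 in aERKO uteri. Between oil conditions it was 0.0015, 0.136 and -0.042, and between the saline times 0.166, 0.212 and -0.018. On that ground 2, 2 and 1 distinct vehicle RNAs were taken for WT, KIKO and aERKO. Treated pools of BPA and HPTE, which are distinct RNAs, also gave low values. These were 0.074 in WT uteri at 2 h and 0.06 in KIKO uteri at 24 h. A low value therefore cannot tell 1 RNA from 2 similar RNAs, and the numbers of distinct RNAs are an assumption.

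Each alternative was run on its own, and some change several settings together, such as eBayes with trend and robust and the fit of single arrays. They were signals processed by the scanner software, no background subtraction, no filter or a filter on all arrays, the mean of all probes of a gene, eBayes with trend and robust, only 1 dye orientation, no vehicle block, the deposited series values, a fit of single arrays with dye effect and slide as random block, BPA and HPTE averaged to 1 value, compound within time as a covariate, only the groups compared, and each compound, genotype or vehicle kind left out in turn.

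The fits were tested on simulated data with 200 planted genes per comparison. For WT at 2 h 62.7%, 95.5% and 95.5% of genes planted at a log2 of 0.6, 1 and 2 were recovered, and 7.14% of calls were false. For the WT minus aERKO difference at 2 h the shares were 43.3%, 79.1% and 95.5%, with 8.23% false. For WT E2 against BPA at 2 h they were 5.97%, 23.9% and 74.2%, with 11.5% false, above the nominal 5%. Random steps used fixed seeds. Software was R 4.3.3, limma 3.58.1, statmod 1.5.0, data.table (1.17.8), python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.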

Results

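Uteri of ovariectomized mice were profiled after an injection of estradiol (E2), bisphenol A (BPA), the methoxychlor metabolite HPTE or vehicle. The mice were wild type (WT), carried estrogen receptor alpha (ERα) with a mutated DNA-binding domain (KIKO), or lacked ERα (aERKO). RNA pools of 3 uteri per treatment, taken 2 or 24 h after injection, were compared with vehicle RNA of the same genotype on 36 2-colour arrays. The 18 conditions (3 genotypes, 3 compounds, 2 times) have 2 dye-swapped arrays each, and the number of arrays limits precision. E2 was given at 250 ng in saline, and BPA and HPTE at 750 µg in sesame oil.

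The dye swaps repeat the same RNA, so a single condition has no replicate pool and no test of its own. The tests treat the 3 compounds in a genotype at 1 time as 3 values (n = 3). They ask which genes respond to estrogenic compounds in each genotype, which responses differ between genotypes, which differ between compounds, and which genes differ between genotypes in vehicle uteri. Responses are log2 ratios of treated over vehicle RNA, given as mean ± SD of the 3 compounds with an adjusted p. Differences are fitted log2 values with a standard error (SE). By the labels the KIKO mice given E2 and those given BPA or HPTE were of different strains, so the 3 KIKO values and E2 contrasts mix strain with compound. A gene rose, fell or changed where its adjusted p was under 0.05.

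In WT uteri 2 h after injection, genes of the acute estrogen response rose sharply. Inhbb, which encodes an activin and inhibin subunit, rose by 5.00 ± 0.25 (adjusted p = 3.48e-08), and the kallikrein gene Klk1b24 by 4.38 ± 0.43 (adjusted p = 2.17e-07). The transcription factor gene Fos rose by 4.33 ± 0.76 (adjusted p = 1.11e-05), and Dok7, which encodes a kinase adaptor, by 4.47 ± 0.08 (adjusted p = 2.63e-10). The largest falls were in Ptgfr, the prostaglandin F receptor gene (-3.40 ± 0.52, adjusted p = 7.15e-08), and Rgs2, a regulator of G protein signalling (-3.15 ± 0.29, adjusted p = 1.97e-07). The progesterone receptor gene Pgr rose by 1.49 ± 0.63 (adjusted p = 0.000147). Esr1, which encodes ERα, did not pass the test (-0.05 ± 0.27, adjusted p = 0.223).

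Of 18 immediate early genes measured in WT uteri at 2 h, 17 rose and 1 did not pass, among them Nr4a1 (4.14 ± 0.55, adjusted p = 9.39e-06) and Ccn1 (3.94 ± 0.30, adjusted p = 2.74e-07). The median of the list was 2.51 (camera adjusted p = 2.07e-11, adjusted p = 0.23 with an estimated correlation between its genes). All 15 early estrogen-induced uterine genes measured rose, with a median of 2.43 (camera adjusted p = 1.39e-13, adjusted p = 0.106 with an estimated correlation). They include Gadd45g (4.20 ± 0.19, adjusted p = 3.56e-08), Cebpb (3.79 ± 0.06, adjusted p = 3.05e-08) and Ramp3 (3.17 ± 0.29, adjusted p = 2.95e-07). Among 16 late estrogen-induced secretory and epithelial genes, 3 rose, 1 fell and 12 did not pass, and the fall turned sign with the mean of all probes. The rises include the water channel gene Aqp5 (3.68 ± 0.12, adjusted p = 2.12e-08) and the arginine deiminase gene Padi1 (3.33 ± 0.27, adjusted p = 1.13e-06).

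Genes for protein production and folding also rose in WT uteri at 2 h. For ribosome biogenesis, 16 of 18 genes rose and 2 did not pass (median 0.94, camera adjusted p = 1.36e-07, adjusted p = 0.281 with an estimated correlation), with Rrs1 at 1.59 ± 0.35 (adjusted p = 3.99e-06) and Gnl3 at 1.49 ± 0.22 (adjusted p = 1.43e-06). Of 18 genes of endoplasmic reticulum (ER) chaperones and the unfolded protein response, 14 rose, 1 fell and 3 did not pass (median 0.86, camera adjusted p = 6.48e-05, adjusted p = 0.342 with an estimated correlation). Atf4 rose by 2.11 ± 0.12 (adjusted p = 2.32e-08) and the chaperone gene Hspa5 by 1.29 ± 0.54 (adjusted p = 0.000125). All 6 heat shock genes rose (median 1.59, camera adjusted p = 6.3e-06, adjusted p = 0.106 with an estimated correlation), for example Hsph1 (2.19 ± 0.72, adjusted p = 2.68e-06) and Dnajb1 (1.79 ± 0.21, adjusted p = 2.15e-08).

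Stromal markers fell in the same WT uteri. All 8 stromal fibroblast markers fell (median -0.88, camera adjusted p = 0.00018, adjusted p = 0.106 with an estimated correlation), including Hoxa11 (-1.52 ± 0.05, adjusted p = 1.98e-07) and Hoxa10 (-1.35 ± 0.60, adjusted p = 1.05e-05), which pattern the uterus. Of 14 Wnt signalling genes, 2 rose, 6 fell and 6 did not pass (camera adjusted p = 0.145). The receptor gene Fzd1 fell (-2.58 ± 0.15, adjusted p = 2.18e-08) and the ligand gene Wnt4 rose (2.51 ± 0.14, adjusted p = 4.02e-06). Of 10 steroid receptor and cofactor genes, 3 rose, 3 fell and 4 did not pass (camera adjusted p = 0.809), with the corepressor gene Nrip1 at 2.13 ± 0.12 (adjusted p = 1.91e-08). Of 7 endothelial markers 4 fell and 3 did not pass, with Cldn5 at -1.32 ± 0.29 (adjusted p = 4.56e-05).

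In all, limma called 8409 of 20764 genes in WT uteri at 2 h, 3932 higher and 4477 lower, and 1425 of them changed at least 2-fold. With the distinct vehicle RNAs as the block, 6823 passed (6712 of them among the 8409). With only the WT 2 h values in the fit, 3865 passed.

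**Figure D1:**
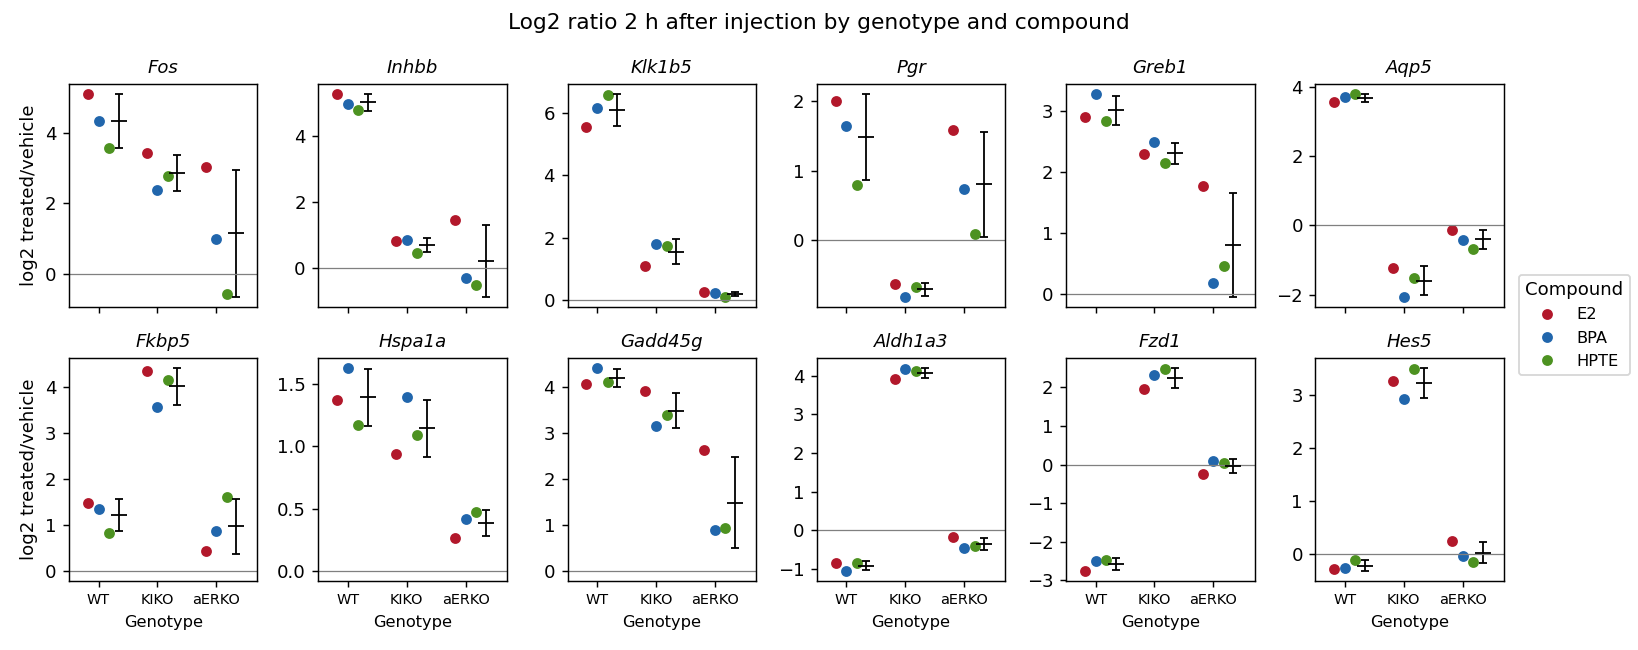
Log2 ratio of treated over vehicle RNA (vertical) of 12 genes 2 h after injection by genotype (horizontal); points are 1 pool pair per compound, bars the mean ± SD of 3 compounds. Aqp5 rose in WT (3.68) and fell in KIKO uteri (-1.60), while Fzd1 fell in WT (-2.58) and rose in KIKO uteri (2.25).

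Genes of cell division were among the largest rises in WT uteri 24 h after injection. Birc5, which encodes survivin, rose by 2.71 ± 0.32 (adjusted p = 0.000192), the cyclin gene Ccnb1 by 2.60 ± 0.53 (adjusted p = 6.42e-06) and the ubiquitin-conjugating enzyme gene Ube2c by 2.55 ± 0.41 (adjusted p = 3.03e-05). The epithelial gene Clca1 rose by 2.76 ± 0.91 (adjusted p = 9.22e-05), with 5 of 6 arrays above 0. The retinaldehyde dehydrogenase gene Aldh1a3 fell (-1.94 ± 1.43, adjusted p = 0.00236), as did the immune cell gene Cd83 (-1.78 ± 1.30, adjusted p = 0.00126). Neither Pgr (0.47 ± 0.51, adjusted p = 0.0892) nor Esr1 (-0.33 ± 0.63, adjusted p = 0.0756) passed the test.

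All 26 mitosis genes rose in WT uteri at 24 h (median 2.26, camera adjusted p = 6.04e-32, adjusted p = 0.18 with an estimated correlation). Of 31 DNA replication genes, 17 rose and 14 did not pass, and 22 rose when adjusted over the list alone (median 0.63, camera adjusted p = 5.4e-10, adjusted p = 0.605 with an estimated correlation). Gins2 rose by 1.47 ± 0.44 (adjusted p = 0.00299) and Gmnn by 1.24 ± 0.92 (adjusted p = 0.00236). Of 12 fibrillar collagen and matrix genes, 9 rose and 3 did not pass (median 0.97, camera adjusted p = 2.83e-06, adjusted p = 0.324 with an estimated correlation), led by Col1a1 (2.11 ± 0.84, adjusted p = 8e-04) and Col1a2 (1.59 ± 0.44, adjusted p = 0.000268).

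Of 12 epithelial cell markers, 7 rose and 5 did not pass at 24 h (median 0.70, camera adjusted p = 3.33e-05, adjusted p = 0.324 with an estimated correlation), with the keratin gene Krt8 at 1.28 ± 0.53 (adjusted p = 0.0031). Of 16 late estrogen-induced secretory and epithelial genes, 7 rose, 1 fell and 8 did not pass, and 11 rose when adjusted over the list alone (median 1.11, camera adjusted p = 0.000867, adjusted p = 0.605 with an estimated correlation). The mucin gene Muc1 rose by 1.24 ± 0.48 (adjusted p = 0.00149). For interferon response genes, 6 of 12 rose and 6 did not pass (median 0.65, camera adjusted p = 0.00435, adjusted p = 0.613 with an estimated correlation), such as Oas1a (1.36 ± 0.50, adjusted p = 0.00457) and Isg15 (1.21 ± 0.55, adjusted p = 0.00496). Of 14 Wnt signalling genes 2 rose, 5 fell and 7 did not pass.

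At 24 h limma called 4200 genes in WT uteri, 2101 higher and 2099 lower, and 444 of them changed at least 2-fold. The count was 2767 with the distinct vehicle RNAs as the block and 733 with HPTE left out. With only the WT 24 h values in the fit limma called 0, with 2882 genes at an unadjusted p under 0.05. The WT values at 2 h and 24 h differed in 9057 genes (4341 higher at 2 h, 4716 lower). Of 26 mitosis genes 25 were lower at 2 h and 1 higher (median -1.56, camera adjusted p = 1.19e-11, adjusted p = 0.396 with an estimated correlation), and of 16 late secretory and epithelial genes 3 were higher and 4 lower (camera adjusted p = 0.451).

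KIKO uteri at 2 h also responded, with other genes in the lead. The kinase inhibitor gene Errfi1 rose by 4.77 ± 0.20 (adjusted p = 1.07e-10), Aldh1a3 by 4.07 ± 0.14 (adjusted p = 2.78e-06), the glucocorticoid-regulated chaperone gene Fkbp5 by 4.01 ± 0.40 (adjusted p = 1.04e-07) and the Notch target gene Hes5 by 3.23 ± 0.29 (adjusted p = 9.07e-08). Foxa2, a transcription factor gene of uterine glands, fell most (-3.16 ± 0.46, adjusted p = 1.1e-06), then Ptgfr (-2.45 ± 0.31, adjusted p = 5.66e-06). Pgr (-0.71 ± 0.09, adjusted p = 0.0756) and Esr1 (-0.06, adjusted p = 0.921) did not pass the test.

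Of the immediate early genes, 15 of 18 rose in KIKO uteri and 3 did not pass (median 1.33, camera adjusted p = 6.98e-09, adjusted p = 0.365 with an estimated correlation), with Nr4a1 at 3.20 ± 0.07 (adjusted p = 0.00026) and Fos at 2.86 ± 0.52 (adjusted p = 0.0016). Of 15 early estrogen-induced uterine genes, 9 rose and 6 did not pass (median 1.32, camera adjusted p = 6.48e-08, adjusted p = 0.316 with an estimated correlation). Cebpb rose by 2.93 ± 0.51 (adjusted p = 1.29e-06) and the receptor cofactor gene Greb1 by 2.30 ± 0.17 (adjusted p = 9e-06). For glucocorticoid response genes, 7 of 8 rose and 1 did not pass (median 1.03, camera adjusted p = 1.84e-05, adjusted p = 0.316 with an estimated correlation), including Sgk1 (2.05 ± 0.19, adjusted p = 5.73e-05), Klf9 (1.29 ± 0.39, adjusted p = 0.00491) and Per1 (1.13 ± 0.16, adjusted p = 0.0325).

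All 6 heat shock genes rose in KIKO uteri (median 1.03, camera adjusted p = 2.26e-05, adjusted p = 0.316 with an estimated correlation), with Hspa1a at 1.14 ± 0.23 (adjusted p = 8.37e-05). Ribosome biogenesis genes rose in 11 of 18 cases and 7 did not pass (median 0.57, camera adjusted p = 2.98e-05, adjusted p = 0.432 with an estimated correlation). Of 18 genes of ER chaperones and the unfolded protein response 6 rose, 1 fell and 11 did not pass (median 0.61, camera adjusted p = 0.00015, adjusted p = 0.432 with an estimated correlation). Wnt4 (3.07 ± 0.24, adjusted p = 5.02e-07) and Fzd1 (2.25 ± 0.26, adjusted p = 4.31e-07) rose, and Aqp5 fell (-1.60 ± 0.42, adjusted p = 0.000166).

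For KIKO uteri at 2 h limma called 4945 genes, 2126 higher and 2819 lower, and 613 of them changed at least 2-fold. With only the KIKO 2 h values in the fit 3166 passed.

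No gene passed the test in KIKO uteri at 24 h. The smooth muscle gene Cnn1 stood at 0.77 ± 0.49 and Col1a2 at 0.63 ± 0.19 (adjusted p = 0.81 and 0.793). The median of the mitosis genes was 0.36 (camera adjusted p = 1.2e-08, adjusted p = 0.751 with an estimated correlation), of smooth muscle markers 0.51 (camera adjusted p = 1.33e-05, adjusted p = 0.751 with an estimated correlation) and of collagen genes 0.36 (camera adjusted p = 1.71e-05, adjusted p = 0.751 with an estimated correlation). In limma 0 genes passed and 1276 had an unadjusted p under 0.05. In simulated data this test recovered 62.7% of genes changed by a log2 of 0.6 and 92.5% of those changed by 1. The test asks what the compounds share, so a response to E2 alone can be missed. Without a test, 283 genes changed at least 2-fold in the KIKO E2 pool at 24 h, against 62 with BPA and 56 with HPTE.

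In aERKO uteri at 2 h few genes changed. The deiodinase gene Dio2 rose by 2.27 ± 0.77 (adjusted p = 0.00455), the stress gene Fam107a by 1.73 ± 0.45 (adjusted p = 0.00455), the kinase gene Sgk1 by 1.53 ± 0.35 (adjusted p = 0.0141) and Gadd45g by 1.48 ± 0.99 (adjusted p = 0.0189). The macrophage genes Mmp12 (-2.14 ± 0.45, adjusted p = 0.0361) and Cd5l (-1.27 ± 0.28, adjusted p = 0.0483) fell. Pgr did not pass (0.80 ± 0.75, adjusted p = 0.141).

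Of 18 immediate early genes 1 rose in aERKO uteri at 2 h, Klf4 (1.10 ± 0.90, adjusted p = 0.0376), and 8 rose when adjusted over the list alone (median 0.54, camera adjusted p = 4.33e-08, adjusted p = 0.445 with an estimated correlation). The medians of that list were 1.48, 0.32 and 0.05 with E2, BPA and HPTE. Of 15 early estrogen-induced uterine genes 2 rose, 10 when adjusted over the list alone (median 0.64, camera adjusted p = 5.88e-10, adjusted p = 0.184 with an estimated correlation). Sgk1 was the only 1 of 8 glucocorticoid response genes that rose, 6 when adjusted over the list alone (median 0.65, camera adjusted p = 6.18e-06, adjusted p = 0.184 with an estimated correlation). Dnajb1 (0.53 ± 0.23, adjusted p = 0.0307) was the only 1 of 6 heat shock genes that rose, 4 when adjusted over the list alone (median 0.42, camera adjusted p = 4.32e-05, adjusted p = 0.184 with an estimated correlation).

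At 2 h limma called 121 genes in aERKO uteri, 104 higher and 17 lower. With the distinct vehicle RNAs as the block 1 passed, without the doubted array 72, and without a vehicle block 589. With only the aERKO 2 h values limma called 0, with 1836 genes at an unadjusted p under 0.05. At 24 h the Wnt coreceptor gene Lrp5 alone passed in limma (1.23 ± 0.13, adjusted p = 0.000424), with 1316 genes at an unadjusted p under 0.05. Without the doubted array limma called 0 genes there, with 2279 at an unadjusted p under 0.05, and with only the aERKO 24 h values 0, with 2460. The mitosis genes had a median of 0.48 at 24 h (camera adjusted p = 1.76e-12, adjusted p = 0.567 with an estimated correlation). Between 2 h and 24 h, 19 genes differed in aERKO uteri (17 higher at 2 h), and the glucocorticoid response genes differed by a median of 0.93 (camera adjusted p = 4.07e-12, 0.0477 with an estimated correlation).

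**Figure D2:**
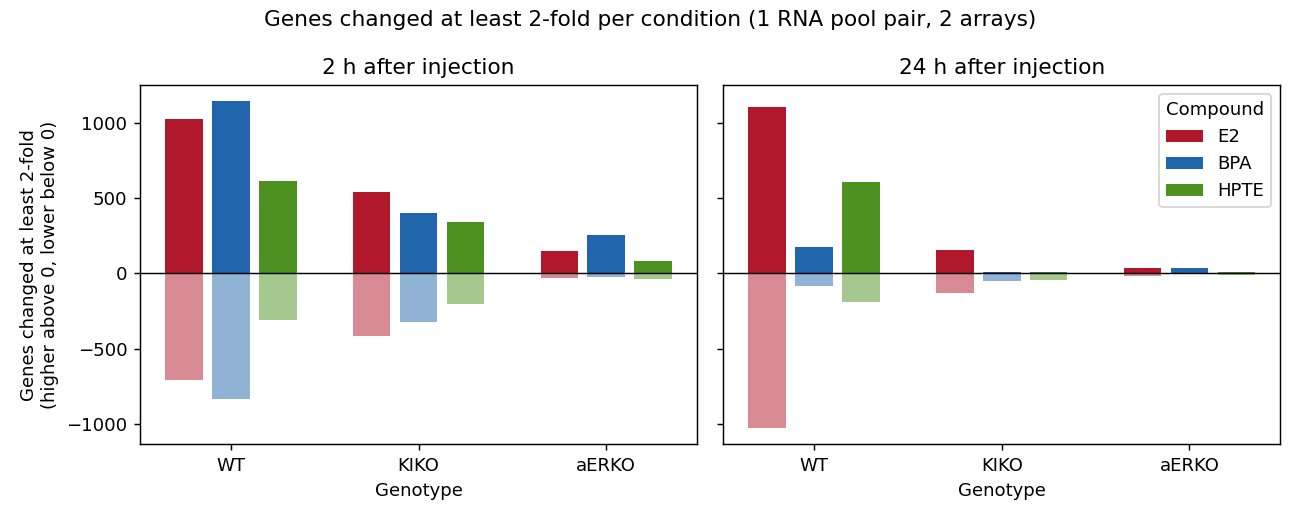
Genes changed at least 2-fold (vertical, higher above 0 and lower below) per genotype (horizontal), compound (colour) and time (panel), each from 1 pool pair without a test. The mean of the 2 arrays is at least 2-fold, with each array at a log2 of 0.5 or more in that direction. E2 at 24 h changed 2133 genes in WT, 283 in KIKO and 53 in aERKO uteri, and BPA at 24 h 256, 62 and 39. Leaving out 1 array of a pair moved 11 of 36 counts by over 1.5 times, those of aERKO uteri at 24 h to 122 with E2 (without the array with treated RNA in Cy5) and with BPA to 104 (without that in Cy5) or 64 (without that in Cy3). With scanner-processed signals all 18 counts rose (1.60 to 4.23 times), at 24 h to 3599, 613 and 214 with E2 and to 535, 123 and 165 with BPA.

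The responses of WT and aERKO uteri at 2 h differed in many genes. The fitted difference was 6.33 (SE 0.53, adjusted p = 5.65e-06) for the kallikrein gene Klk1b5, 5.09 (SE 0.48, adjusted p = 1.15e-05) for Inhbb and 4.35 (SE 0.23, adjusted p = 4.38e-08) for Dok7. Rgs2 (-2.83, SE 0.38, adjusted p = 0.000186) and the integrin gene Itgb8 (-2.84, SE 0.45, adjusted p = 0.000604) were lower in the WT response. Pgr did not differ past the test (0.78, SE 0.38, adjusted p = 0.181).

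Of 18 immediate early genes, 11 were higher in the WT response at 2 h and 7 did not pass (median 1.63, camera adjusted p = 3.46e-09, adjusted p = 0.302 with an estimated correlation), with Ccn1 at 3.55 (SE 0.46, adjusted p = 0.000148) and Fos at 3.55 (SE 0.78, adjusted p = 0.00596). Of 15 early estrogen-induced uterine genes 11 were higher and 4 did not pass (median 1.76, camera adjusted p = 7.51e-13, adjusted p = 0.163 with an estimated correlation), with Cebpb at 3.09 (SE 0.34, adjusted p = 3.86e-05). For ribosome biogenesis 12 of 18 genes were higher and 6 did not pass (median 0.83, camera adjusted p = 2.46e-07, adjusted p = 0.302 with an estimated correlation). Of 6 heat shock genes 5 were higher and 1 did not pass (median 1.17, camera adjusted p = 2.76e-05, adjusted p = 0.163 with an estimated correlation). Of 8 stromal fibroblast markers 4 were lower and 4 did not pass (median -0.63, camera adjusted p = 0.000686, adjusted p = 0.163 with an estimated correlation), with Hoxa10 at -1.44 (SE 0.26, adjusted p = 0.00181).

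At 24 h, 19 of 26 mitosis genes were higher in the WT than in the aERKO response, and 26 when adjusted over the list alone (median 1.66, camera adjusted p = 9.75e-25, adjusted p = 0.189 with an estimated correlation). Ccnb1 differed by 2.09 (SE 0.34, adjusted p = 0.00615) and the spindle gene Tpx2 by 2.01 (SE 0.32, adjusted p = 0.00612). Of 12 epithelial cell markers 6 were higher and 6 did not pass (median 0.87, camera adjusted p = 2.1e-08, adjusted p = 0.189 with an estimated correlation), with Krt19 at 1.45 (SE 0.22, adjusted p = 0.00526). Of 12 collagen and matrix genes 3 were higher, 9 when adjusted over the list alone (median 0.84, camera adjusted p = 2.31e-05, adjusted p = 0.438 with an estimated correlation). With the distinct vehicle RNAs as the block limma called 0 of these mitosis, epithelial and collagen genes, with 24, 10 and 8 at an unadjusted p under 0.05.

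The WT and aERKO responses differed in 3795 genes at 2 h (1836 higher, 1959 lower) and 869 at 24 h (487 higher, 382 lower). With the distinct vehicle RNAs as the block the counts were 1217 and 4. With scan day as a fixed block they were 2357 and 304, and with only the 2 groups in the fit 852 and, in limma, 0 (2957 at an unadjusted p under 0.05).

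The KIKO response at 2 h exceeded the aERKO response in the genes that led it. Aldh1a3 differed by 4.35 (SE 0.51, adjusted p = 0.00018), Errfi1 by 3.94 (SE 0.24, adjusted p = 2.6e-07), Hes5 by 3.42 (SE 0.31, adjusted p = 1.76e-05), and Wnt4 by 3.04 (SE 0.37, adjusted p = 0.000243). Dio2 (-3.17, SE 0.44, adjusted p = 0.00076), Aqp5 (-1.27, SE 0.33, adjusted p = 0.0431) and Pgr (-1.61, SE 0.38, adjusted p = 0.0293) were lower in the KIKO response. Of 18 immediate early genes 3 were higher and 15 did not pass (median 0.47, camera adjusted p = 0.000651, adjusted p = 0.601 with an estimated correlation). Of 8 glucocorticoid response genes 1 was higher and 7 did not pass, and that gene was Fkbp5 (3.04, SE 0.36, adjusted p = 0.000168).

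At 2 h 726 genes differed between the KIKO and aERKO responses, 411 higher and 315 lower, and 158 with the distinct vehicle RNAs as the block. At 24 h Lrp5 alone differed (-1.50, SE 0.17, adjusted p = 0.00364). Without the doubted array limma called 0 genes, with 1142 at an unadjusted p under 0.05, with trend and robust eBayes 0, with 762, and with only the 2 groups in the fit 0, with 1212. In simulated data that test recovered 37.3% of differences of 0.6 and 74.6% of differences of 1.

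The WT and KIKO responses at 2 h differed in direction as well as size. Aqp5 (5.53, SE 0.33, adjusted p = 1.19e-07), Klk1b5 (5.03, SE 0.53, adjusted p = 3.05e-05), Inhbb (4.66, SE 0.48, adjusted p = 2.15e-05), Pgr (2.39, SE 0.38, adjusted p = 0.000875) and Nrip1 (2.15, SE 0.18, adjusted p = 2.94e-06) were higher in the WT response. Aldh1a3 (-5.36, SE 0.51, adjusted p = 1.2e-05), Fzd1 (-5.11, SE 0.24, adjusted p = 1.56e-08), Hes5 (-3.80, SE 0.31, adjusted p = 2.3e-06) and Fkbp5 (-2.71, SE 0.36, adjusted p = 0.000184) were lower. Of 3607 genes that changed in both genotypes 153 changed in opposite directions, 69 of them higher in WT and lower in KIKO uteri.

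Of 15 early estrogen-induced uterine genes 6 were higher in the WT than in the KIKO response and 9 did not pass (median 0.91, camera adjusted p = 6.02e-08, adjusted p = 0.274 with an estimated correlation). Of 18 immediate early genes 5 were higher and 13 did not pass (median 1.03, camera adjusted p = 0.000142, adjusted p = 0.557 with an estimated correlation), for example Ier3 (2.66, SE 0.36, adjusted p = 0.000219). Of 8 stromal fibroblast markers 3 were lower and 5 did not pass (median -0.60, camera adjusted p = 0.000142, adjusted p = 0.24 with an estimated correlation), with Hoxa11 at -1.38 (SE 0.17, adjusted p = 8.56e-05). Of 8 glucocorticoid response genes 2 were lower and 6 did not pass (camera adjusted p = 0.0551).

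At 24 h, 16 of 26 mitosis genes were higher in the WT than in the KIKO response, and 26 when adjusted over the list alone (median 1.81, camera adjusted p = 2.67e-40, adjusted p = 0.0847 with an estimated correlation). Ccnb1 differed by 2.54 (SE 0.34, adjusted p = 0.00195) and the kinase gene Nek2 by 2.19 (SE 0.28, adjusted p = 0.00193). Clca1, above 0 on 5 of 6 WT arrays, differed by 2.86 (SE 0.46, adjusted p = 0.00749) and Cd83 by -2.25 (SE 0.43, adjusted p = 0.0264). Of 12 epithelial cell markers Epcam alone passed (1.01, SE 0.16, adjusted p = 0.00754), and 8 were higher when adjusted over the list alone (median 0.75, camera adjusted p = 5.2e-08, adjusted p = 0.133 with an estimated correlation).

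The WT and KIKO responses differed in 1692 genes at 2 h (961 higher, 731 lower) and 138 at 24 h (123 higher, 15 lower). With the distinct vehicle RNAs as the block the counts were 1011 and 62, and with only the 2 groups in the fit 767 and, in limma, 0 (1447 at an unadjusted p under 0.05). The WT minus KIKO difference at 2 h minus that at 24 h passed in 2433 genes, with Aqp5 at 4.35 (SE 0.35, adjusted p = 2.86e-06) and Fzd1 at -4.03 (SE 0.26, adjusted p = 3.62e-07).

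**Figure D3:**
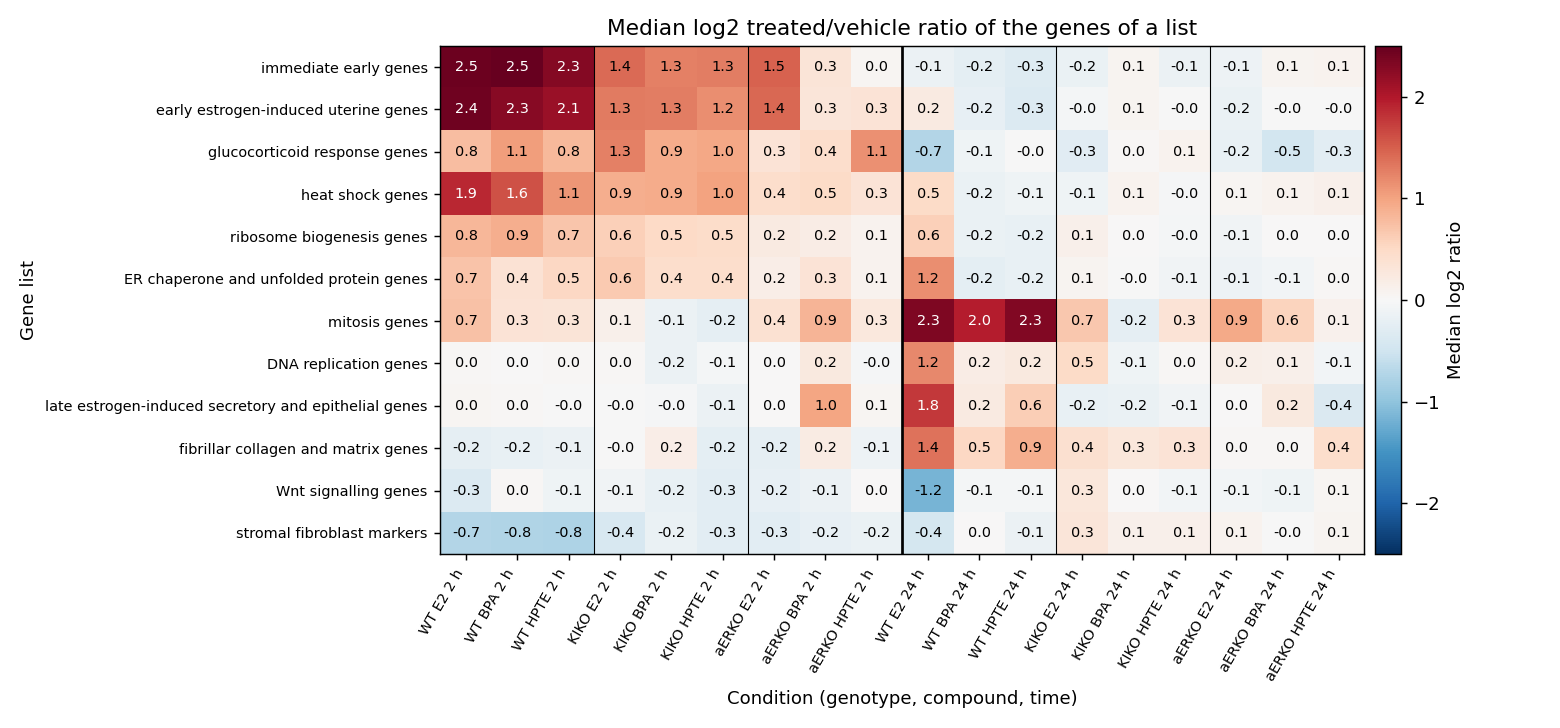
Median log2 ratio of treated over vehicle RNA (colour and printed number) of 12 gene lists (vertical) in each of the 18 conditions (horizontal), each 1 pool pair on 2 arrays. Immediate early genes at 2 h stood at 2.45, 2.53 and 2.29 with E2, BPA and HPTE in WT uteri and at 1.48, 0.32 and 0.05 in aERKO uteri.

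In WT uteri each compound is 1 pool, so differences between compounds there are values of 1 pool against 1, given without a test. At 24 h the E2 pool lay above the BPA pool by 3.46 for the alkaline phosphatase gene Alpl, 4.27 for the amine oxidase gene Aoc1, 2.29 for the replication licensing gene Cdc6 and 2.35 for the chaperone gene Hyou1. For the Wnt inhibitor gene Dkk2 it lay below (-1.58). Against the HPTE pool the values were 3.29 for Alpl and 2.21 for Hyou1.

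The 31 DNA replication genes stood higher in the E2 pool by a median of 1.09 against BPA and 1.03 against HPTE at 24 h in WT uteri. The 18 genes of ER chaperones and the unfolded protein response had a median of 1.38 against BPA, and the 14 Wnt signalling genes -1.09 against both. The mitosis genes had a median of 0.39 against BPA.

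**Figure D4:**
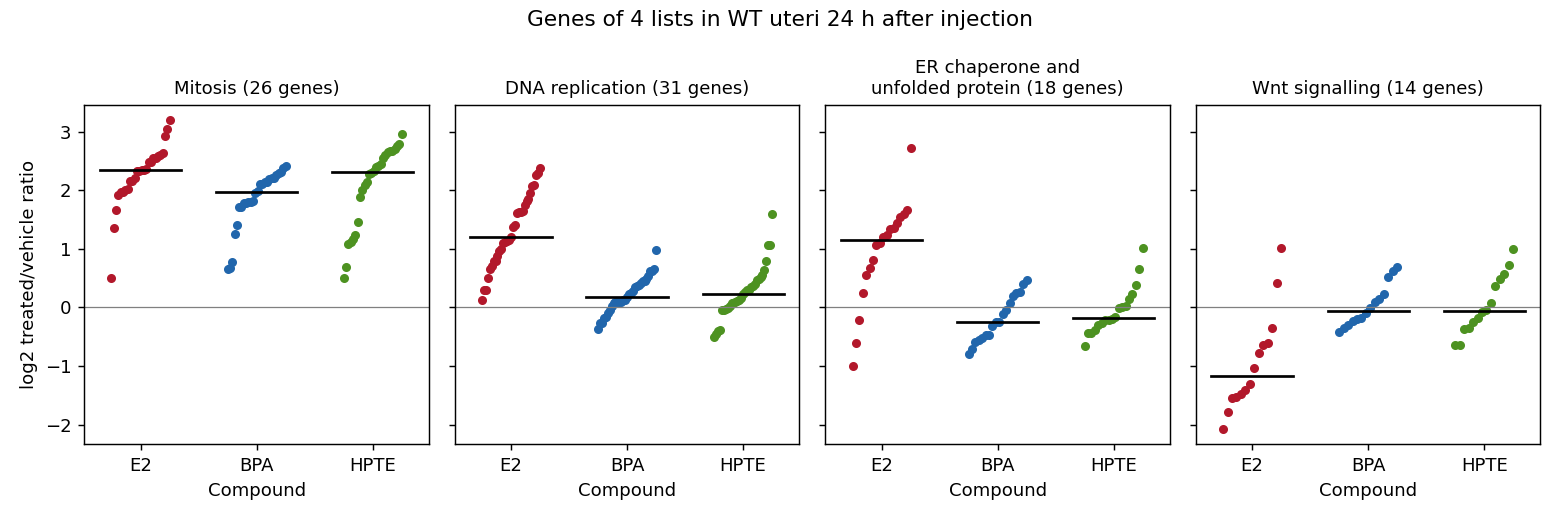
Log2 ratio of treated over vehicle RNA (vertical) of the genes of 4 lists in WT uteri at 24 h by compound (horizontal); points are genes of 1 pool pair, lines medians. DNA replication genes had medians of 1.20, 0.18 and 0.24 with E2, BPA and HPTE, while mitosis genes had 2.34, 1.97 and 2.31.

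A limma fit can set these single WT pools against each other only with the spread of KIKO and aERKO uteri, where 0 and 1 genes changed at 24 h. On that spread 2329 genes passed between E2 and BPA at 24 h and 1837 between E2 and HPTE, and at 2 h limma called 0 and 1, with 2795 and 1911 at an unadjusted p under 0.05. No gene is called from these counts, since WT uteri lack a replicate pool per compound. E2 and the other compounds also differ in dose and vehicle.

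BPA and HPTE, given at the same dose in the same vehicle, were set against each other over the 3 genotypes. In that test limma called 0 genes at 2 h and 0 at 24 h, with 1158 and 1110 at an unadjusted p under 0.05. The difference was 0.46 for Pgr (95% interval 0.06 to 0.85, adjusted p = 0.877) and 1.39 for Egr3 (95% interval 0.58 to 2.19, adjusted p = 0.86) at 2 h, and -0.57 for the smooth muscle gene Smtn (95% interval -0.89 to -0.25, adjusted p = 0.806) at 24 h. A missed test does not show that the compounds act alike. Between the single WT pools 10 genes passed at 2 h and 1 at 24 h on the borrowed spread, and no gene is called from them either.

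For BPA minus HPTE at 24 h over the 3 genotypes the smooth muscle markers had a median of -0.53, and limma called 0 of 8, 4 when adjusted over the list alone (camera adjusted p = 9.11e-07, lost at an adjusted p = 0.59 with an estimated correlation). E2 against the mean of BPA and HPTE over the genotypes gave 0 genes in limma at 2 h and 0 at 24 h, with 668 and 2851 at an unadjusted p under 0.05. Its DNA replication genes had a median of 0.57 at 24 h (camera adjusted p = 1.59e-17, adjusted p = 0.606 with an estimated correlation), 23 of 31 passing when adjusted over the list alone.

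In vehicle uteri many genes differed between the genotypes, in values of single channels. Scan day goes in part with genotype: the aERKO arrays share a day with the WT oil arrays and with no KIKO array. The KIKO oil arrays were scanned on a day of their own, and no scan day block was fitted to vehicle uteri. Strain background and animal set also differ between the genotypes. WT exceeded aERKO uteri in the Wnt inhibitor gene Wif1 (4.38, SE 0.07, adjusted p = 5.15e-09), the steroid dehydrogenase gene Akr1c14 (3.80, adjusted p = 9.96e-06) and Esr1 (2.74, adjusted p = 3.74e-07), and was lower in the muscle gene Tnnc2 (-5.16, SE 0.12, adjusted p = 8.25e-08). WT exceeded KIKO uteri in Wif1 (4.23, adjusted p = 6.93e-09), Dio2 (3.43, adjusted p = 2.68e-06) and Esr1 (1.11, adjusted p = 4.63e-05), and was lower in the cilia genes Fam183b (-5.72, adjusted p = 2.92e-06) and Tekt1 (-5.44, adjusted p = 2.8e-06). Wif1 was well above background on 3 of 12 vehicle arrays in aERKO and on 3 of 12 in KIKO uteri, which leaves the size of its differences uncertain. Pgr was higher in WT than in aERKO (0.53, adjusted p = 0.00343) and KIKO uteri (0.74, adjusted p = 0.000387).

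Of 26 mitosis genes 21 were higher in WT than in aERKO vehicle uteri (median 0.88, camera adjusted p = 2.67e-15, adjusted p = 0.136 with an estimated correlation) and 21 were higher in WT than in KIKO vehicle uteri (median 0.95, camera adjusted p = 1.7e-16, adjusted p = 0.115 with an estimated correlation). Of 12 epithelial cell markers 1 was higher and 9 lower in WT against aERKO (median -0.59, camera adjusted p = 6.88e-05, adjusted p = 0.0657 with an estimated correlation), and 1 higher and 9 lower against KIKO (median -1.02, camera adjusted p = 1.5e-06, 0.0386 with an estimated correlation). Of 8 glucocorticoid response genes 5 were lower in WT than in aERKO vehicle uteri (median -0.91, camera adjusted p = 1.32e-05, adjusted p = 0.0657 with an estimated correlation), with Fkbp5 at -1.79 (adjusted p = 4.05e-05), and 4 were lower than in KIKO (median -0.85, camera adjusted p = 0.000389, adjusted p = 0.115 with an estimated correlation). Of 8 adipocyte markers 6 were lower in WT than in aERKO (median -1.33, camera adjusted p = 1.32e-05, adjusted p = 0.201 with an estimated correlation), such as Cidec (-1.96, adjusted p = 0.000769).

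Markers of other cells differed between WT and KIKO vehicle uteri in both directions. Of 8 smooth muscle markers 4 were higher in WT and 4 did not pass, and 1 of the 4 turned sign with the mean of all probes (median 0.38, camera adjusted p = 0.0283, adjusted p = 0.463 with an estimated correlation), with Smtn at 1.05 (adjusted p = 0.00339) and Actg2 at 0.84 (adjusted p = 0.00288). Of 12 collagen and matrix genes 8 were higher and 4 did not pass (median 0.58, camera adjusted p = 0.00061, adjusted p = 0.162 with an estimated correlation). Of 8 stromal fibroblast markers 2 were higher and 6 did not pass (median 0.24, camera adjusted p = 0.0637), with Lum at 1.75 (adjusted p = 2.8e-06). Of 8 adipocyte markers 3 were lower in WT and 5 did not pass (median -0.68, camera adjusted p = 0.0256, adjusted p = 0.463 with an estimated correlation), with Lep at -0.80 (adjusted p = 0.00207). Of 4 red blood cell markers 3 were lower and 1 did not pass (median -0.60, camera adjusted p = 0.0245, adjusted p = 0.179 with an estimated correlation), with Hba-a1 at -0.71 (adjusted p = 0.00919).

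Vehicle uteri differed in 3813 genes between WT and aERKO (1777 higher, 2036 lower) and 4201 between WT and KIKO (2076 higher, 2125 lower), with the 3 vehicle labels of a genotype as 3 values. The dye swaps point to only 2, 2 and 1 distinct vehicle RNAs in WT, KIKO and aERKO. With 1 value per distinct RNA aERKO has 1 value and no spread of its own. No gene is therefore called against it on that basis. If the aERKO labels share 1 RNA, the 3813 calls against aERKO rest on repeats of it. Against KIKO 423 genes passed with 1 value per distinct RNA, Wif1 and Slc26a7 (3.82) among them. Against aERKO the Slc26a7 difference was 3.52. Dio2, Fam183b and Tekt1 also passed against KIKO (adjusted p = 0.00995 each). Esr1 (adjusted p = 0.0648) and Pgr (adjusted p = 0.103) did not pass against KIKO. The calls of Wif1, Akr1c14, Esr1, Tnnc2 and Pgr against aERKO would then rest on 1 aERKO RNA. So would the calls of 21 mitosis, 10 epithelial, 5 glucocorticoid response and 6 adipocyte genes against aERKO. Against KIKO 7 of 21 mitosis, 2 of 10 epithelial, 2 of 4 glucocorticoid response and 1 of 2 stromal genes kept their call. Of 4 smooth muscle, 8 collagen and matrix, 3 adipocyte and 3 red blood cell genes limma called 0, with 3, 6, 1 and 1 genes of these lists at an unadjusted p under 0.05.

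Among the camera calls given above, that of the epithelial cell markers in WT against KIKO vehicle uteri holds with an estimated correlation. That of the glucocorticoid response genes at 2 h against 24 h in aERKO uteri holds too. Every other camera call given above was lost. On the borrowed spread, the Wnt signalling genes in WT uteri at 24 h also held for E2 against BPA and against HPTE. No call is taken from that, since each compound there is a single pool. The epithelial call takes the 3 vehicle labels of a genotype as separate values. The dye swaps point to only 2 distinct vehicle RNAs in WT and 2 in KIKO, so its p may count the same RNA more than once.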

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

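For the tests weighed here, the predictions on the shared vehicle RNA, carried-over RNA, scan day in the WT and KIKO contrast and a general shift of arrays were chosen only after the result was seen, and the other tests before. In aERKO uteri, which lack ERα, 121 genes changed at 2 h, with a median change of 0.729 in their own direction, 72 genes without the doubted array, 1 with the distinct vehicle RNAs as the block (fitted median 0.74 to 0.73, median SE 0.13 to 0.19, so the wider SE ended the calls), and in limma 0 with only the aERKO values (1836 at an unadjusted p under 0.05). A shared vehicle RNA that stands apart would put the same change at 24 h, where it was 0.168 (95% interval 0.136 to 0.227). That argues against such a vehicle RNA as the whole cause. Of the 121 genes 103 kept their sign at 24 h and 17 kept at least 0.75 of the 2 h change, so a part stays open. RNA of WT uteri carried into the E2 pool would show in genes outside the early lists too, and these reached 4.81% of the WT rise (95% interval 2.28 to 9.40, 50 genes) against 36.8% for early genes (20.6 to 46.8, 18 genes), which argues against it. A response to injection or handling is a possible explanation, since the same genes moved by a median of 0.484 in WT (0.363 to 0.681) and 0.548 in KIKO uteri (0.419 to 0.715). But 62.7% and 68.1% of all genes also share a sign there, and a shared estrogen response without full-length ERα would give the same. Vehicle mice were injected too, so handling would show only where vehicle and treated uteri were taken at different times after injection. The dye swaps point to 1 aERKO vehicle RNA for both times but cannot show it. Residual receptor activity stays open and was not tested, as Esr1 signal in aERKO vehicle uteri (11.68, against 14.38 in WT and 13.41 in KIKO) was well above background on 12 of 12 arrays and the position of the probe was not determined.

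At 2 h 153 genes changed in opposite directions in WT and KIKO uteri, with the difference past the test. If vehicle RNAs that differ between the genotypes made the pattern, the opposite signs would vanish in the values of 2 h minus 24 h, and 88.9% (136 of 153) kept them, which argues against it. For scan day or slide, 57.5% (292 of 508) of genes opposite in the BPA and HPTE pools were also opposite in the E2 pools on shared slides, a share that cannot tell. Strain background and animal set differ between the genotypes and stay open. By the labels the KIKO mice of the E2 set and of the BPA and HPTE set also differ in strain, so the means of KIKO uteri and the E2 contrasts that include them mix strains.

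In WT uteri at 24 h 30 of 31 DNA replication genes stood higher with E2 than with BPA and HPTE (median 1.04). The saline and oil vehicle RNAs differed in these genes by 0.031 (95% interval -0.140 to 0.325), which argues against unlike vehicle RNAs as the cause. E2 was always given in saline and BPA and HPTE in sesame oil. An effect of the vehicle on the action of a compound therefore cannot be told apart from the compound. The 2 E2 arrays, scanned on 2 days, gave 1.32 and 1.34, which argues against 1 day of the E2 arrays, but the BPA and HPTE arrays of WT uteri at 24 h were scanned on another day, which cannot be told apart from the compound. Of 10000 random lists of matched intensity 0% reached the difference (highest 0.42), which cannot tell on a general shift, since each array was centred on 0. Dose and time course of the compounds stay open.

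Immediate early genes differed by a median of 1.63, early estrogen-induced uterine genes by 1.76 and heat shock genes by 1.17 between WT and aERKO responses at 2 h, and mitosis genes by 1.66 at 24 h. Mitosis genes differed by 1.81 between WT and KIKO responses at 24 h. Each of these camera calls was lost with an estimated correlation (adjusted p = 0.302, 0.163, 0.163, 0.189 and 0.0847). With the distinct vehicle RNAs as the block limma called 0 of the 19 mitosis genes between WT and aERKO, with 24 at an unadjusted p under 0.05, and 10 of 16 between WT and KIKO.

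For regrouped samples, 10 splits are too few for a share under 0.05. Between 2 genotypes every other split mixes them, so a real difference enters the spread and lowers the count. Low counts in the other splits therefore say little on chance. Between WT and aERKO 3795 genes at 2 h stand against at most 1 in the other splits, and 869 at 24 h against 0, each with 1 of 10 splits as high. Between KIKO and aERKO 726 at 2 h stand against at most 1, and 1 at 24 h against 0. Between WT and KIKO 1692 and 138 stand against 0 each. In vehicle uteri 3813 for WT against aERKO stand against 0, and 4201 for WT against KIKO against at most 14. These 2 take the 3 vehicle labels of a genotype as separate values, though the dye swaps point to 2, 2 and 1 distinct RNAs. With 1 value per distinct RNA 423 genes passed for WT against KIKO. No gene is called on that basis against aERKO, which then has 1 value. For BPA minus HPTE 10 of 10 splits were as high at both times (limma called 0 genes, at most 4 in other splits at 2 h and 0 at 24 h, with 1158 and 1110 genes at an unadjusted p under 0.05). For E2 minus the mean of BPA and HPTE 81 of 81 splits were as high (0 genes, at most 16 in other splits at 2 h and 0 at 24 h, with 668 and 2851 at an unadjusted p under 0.05). A real count of 0 makes every split as high whatever the data, so these splits say nothing on chance.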

How the results depend on the processing

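Tests with distinct vehicle RNAs or scan day as a block, without the doubted array and on the 10 added contrasts were chosen only after the result was seen. Signal over background limits genes dim in 1 genotype, such as Cyp1a1, lower in WT than in KIKO vehicle uteri by at least 1.84-fold, and Ccne2 in KIKO uteri at 2 h, where the rise is at least 1.52-fold. A fit with replicate pools was not run because each condition has 1 pool, and the cause of the moves below was not tested. Paired values are for 2 h and 24 h. With only the groups compared, WT gave 3865 and 0, KIKO at 2 h 3166, aERKO 0 and 0, WT minus aERKO 852 and 0, KIKO minus aERKO 161 and 0, and WT minus KIKO 767 and 0. Without a vehicle block WT at 24 h gave 6389, aERKO 589 and 28, WT minus aERKO at 24 h 2986, KIKO minus aERKO 1564 and 3, WT minus KIKO 2551 and 859, and in WT uteri E2 minus BPA 591 and 5250, E2 minus HPTE 141 and 5253, and BPA minus HPTE 6 and 0. Without that block 2 h minus 24 h gave 2485 in KIKO, 5 in aERKO and 1050 for WT minus KIKO. Dye swaps of the same RNA count as separate values in the array level fit, which also drops the vehicle block. Its counts therefore rest on repeats of the same RNA. The array level fit gave 7311 for WT at 24 h, 363 for KIKO at 24 h, 3036 and 517 for aERKO, 7582 and 5608 for WT minus aERKO, 3595 and 122 for KIKO minus aERKO, 5332 and 2629 for WT minus KIKO, 42 for BPA minus HPTE at 2 h, and 144 and 3639 for E2 minus the mean of BPA and HPTE. Distinct vehicle RNAs as the block gave 2767 for WT at 24 h, 1 for aERKO at 2 h, 1217 and 4 for WT minus aERKO, 158 for KIKO minus aERKO at 2 h, and 1011 and 62 for WT minus KIKO. With 1 value per distinct RNA vehicle uteri gave 19 (WT minus aERKO) and 423 (WT minus KIKO). In that fit aERKO has 1 value and no spread of its own, so no gene is called from its count against aERKO. Scan day as a random block gave 2740 for WT at 24 h, 2 for aERKO at 24 h, 7847 and 5725 for WT minus aERKO, 3112 and 4 for KIKO minus aERKO, and 3243 and 1107 for WT minus KIKO. As a fixed block it gave 2587 for WT at 24 h, 964 and 14 for aERKO, 2357 and 304 for WT minus aERKO, and 72 and 445 at 24 h for KIKO minus aERKO and WT minus KIKO. BPA and HPTE averaged to 1 value gave 21 and 0 for aERKO, and 392, 0 and 89 at 24 h for WT minus aERKO, KIKO minus aERKO and WT minus KIKO. Compound within time as a covariate gave 27 and 2 for aERKO. Trend and robust eBayes gave 72 for aERKO at 2 h and 0 for KIKO minus aERKO at 24 h. Without the doubted array aERKO gave 72 and 0, KIKO minus aERKO at 24 h 0 and WT E2 minus HPTE at 2 h 0. Scanner-processed signals gave 2 and 72 at 24 h for KIKO minus aERKO and WT minus KIKO, and 4 for WT BPA minus HPTE at 2 h. The deposited series values gave 2, 2 and 78 at 24 h for aERKO, KIKO minus aERKO and WT minus KIKO. A filter on all arrays gave 472 for KIKO minus aERKO at 2 h and 84 for WT minus KIKO at 24 h. Leaving out 1 dye orientation, compound or vehicle kind gave 733 to 7832 for WT at 24 h, 0 to 69 for KIKO at 24 h, 6 to 1587 and 0 to 853 for aERKO, 2774 to 7544 and 22 to 5422 for WT minus aERKO, 387 to 3055 and 0 to 65 for KIKO minus aERKO, 1045 to 5648 and 43 to 3754 for WT minus KIKO, and 693 to 13127 and 1294 to 11290 for vehicle uteri (WT minus aERKO, WT minus KIKO). In all 20 of 21 alternatives lay within 1.5 times for WT and for KIKO at 2 h, and 13 of 21 for WT at 24 h. The untested 2-fold counts moved in all 18 conditions with scanner-processed signals (1.60 to 4.23 times). On leaving out 1 array of a pair 11 of 36 moved (0.857 to 6.80 times), WT HPTE to 1748 and 1379, KIKO HPTE at 24 h to 117, aERKO E2 to 322 and 122, aERKO BPA to 540 and to 104 or 64, and aERKO HPTE to 209 and to 136 or 39. Of the genes open to naming and set against the alternatives, 5 values turned sign in an alternative and are named only here. With the mean of all probes Sprr2a1 in WT uteri at 2 h went from -0.44 to 0.075 and Tagln in WT minus KIKO vehicle uteri from 0.37 to -0.01. On leaving 1 part out Ccl2 in WT uteri at 2 h ranged from -0.142 to 1.47, Gsta1 in WT uteri at 24 h from -0.051 to 0.963, and Cd3e in WT minus KIKO vehicle uteri from -0.021 to 0.61.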

Other observations

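The genes below were named after their values were seen, and the tests on them were chosen only after the result was seen. Cilia genes differed between WT and KIKO vehicle uteri. Of 26 cilia genes measured, 20 were lower in WT than in KIKO vehicle uteri, 0 higher and 6 did not pass (median -1.74), and 12 were lower with 1 value per distinct vehicle RNA. Between WT and aERKO 2 were lower, 1 higher and 23 did not pass (median -0.09). With 1 value per distinct vehicle RNA aERKO has 1 value, so no test against it is given. KIKO was not tested against aERKO. Drc1, which encodes a dynein regulator, had a log2 intensity of 12.86 (oil) and 11.40 (saline) in KIKO, 7.41 and 7.50 in WT and 7.63 in aERKO uteri. Foxj1, which drives ciliated cell formation, stood at 11.57 and 10.56 in KIKO, 10.31 and 9.37 in WT and 7.93 in aERKO uteri. Ovgp1, a gene of oviduct secretory cells, did not differ past the test between WT and KIKO (0.45, adjusted p = 0.134).

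The aERKO E2 pool at 2 h stood apart from the BPA and HPTE pools in immediate early genes, without a test as it is 1 pool. Egr3 stood at 4.23, Nr4a1 at 3.88, Egr4 at 3.74, Fos at 3.02 and Egr1 at 2.78 on the log2 scale, against 1.25 and 0.02 for Egr3 and 1.01 and -0.55 for Fos with BPA and HPTE. Pgr stood at 1.59 and Greb1 at 1.77 with E2, while Klk1b5 (0.26) and Aqp5 (-0.12), high in WT uteri, stayed near 0.

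In WT uteri at 2 h the nuclear receptor gene Pparg rose by 2.62 ± 0.29 (adjusted p = 1.81e-06) and the dioxin-responsive gene Tiparp by 3.03 ± 0.18 (adjusted p = 4.53e-08), while Cyp1b1 fell (-1.54, adjusted p = 0.000523). Tiparp rose in KIKO uteri too (2.37 ± 0.30, adjusted p = 7.61e-07). The metallothionein genes Mt1 (-1.61, adjusted p = 3.16e-06) and Mt2 (-1.39, adjusted p = 1.61e-05) were lower in WT than in KIKO vehicle uteri, as was the secretory gene Ltf (-2.25, adjusted p = 5.7e-05).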
